A study of Mus musculus with 6 samples.

How the data were processed

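RNA of small-intestinal epithelium from 3 Maf double knockout mice (DKO) and 3 control mice at postnatal day 7 was isolated with a Qiagen kit and sequenced and analysed by a service company, per the labels' protocols. The submitters' processing notes name STAR, HTSeq, TopHat, DESeq2 and edgeR, with no version or role, and the genome build and the strandedness of the counting are not given in the sources used here. One table was deposited for the whole series. It gives for each listed gene the read count, a normalized count and an FPKM value per library, and the authors' log2 fold change, p-value and adjusted p for DKO against control, per the file headers. Of the 3425 listed gene identifiers, 3424 were found in the reference annotation GENCODE M21 and 3296 had identical positions there, so the coordinates of the table fit GRCm38.

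The deposited table holds only genes with an adjusted p of at most 0.0498, out of 15021 genes over which the authors had adjusted, a number recovered from the ratio of the deposited adjusted p to the deposited p-value and rank. The table thus holds 22.8% of the adjusted genes. The deposited read counts are whole numbers and no listed gene had 0 reads in every library. The deposited normalized counts, a signal scaled by the authors before deposit, are the read counts divided by a size factor per library (0.831 to 1.15), and the library totals follow from the deposited FPKM values, counts and gene lengths. The ratio of size factor to recovered total was the same in every library to within rounding. A scaling by library total would give this, and so would FPKM values computed from the size factors. The kind of scaling therefore cannot be told. Recovered totals were 16423204, 14441272 and 17325070 in DKO replicates 1 to 3 and 18169623, 19973471 and 19256544 in control replicates 1 to 3. They are read totals only if the FPKM values had been computed from library totals. Pairs of libraries within a group differed well beyond sampling noise (chi-square per degree of freedom 25.1 to 42.6), and each was used as 1 replicate. Per-library precision is given by the SD between mice, and values of genes with few counts carry counting error beside it.

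The samples were grouped by the genotype in the labels, and every test outside the alternatives had n = 3 per group. The groups, the test, the gene lists, the rule for named genes and the alternatives other than those said to be added were fixed before the data were examined. Differences between DKO and control were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided) on the deposited counts. The design had called for TMM scaling, but a table of called genes alone gives no neutral genes to scale on, so the deposited size factors and library totals were used, and TMM over the listed genes was an alternative added after the table was seen. filterByExpr removed 48 listed genes and 3377 were tested, with a common dispersion of 0.0282. The Benjamini-Hochberg adjustment was made over 15021 genes with every gene outside the list treated as not passing, and the threshold was 0.05. Genes outside the list could therefore not be called. Dispersions were estimated from the listed genes alone, so the number called can lie above or below that of a fit of all genes. The listed genes had been selected on these libraries, so the p-values of listed genes are not independent of the authors' test. The standard error of a log2 fold change was taken as its size divided by the square root of the F value. Fold values are ratios of group means of normalized counts.

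The 37 gene lists hold 574 distinct genes together with the targeted and sex-linked genes, of which 276 were listed. Lists with at least 4 tested members were compared with the other listed genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 26 lists. The alternatives were a correlation estimated per list, a preset correlation of 0.05 and rank versions. Calls adjusted over the list alone used the size of the whole list. Listed genes had already passed the authors' test, and 3375 of the 3377 tested had an unadjusted edgeR p under 0.05. Most listed members therefore pass this adjustment by selection, and its counts add no separate support. Whether a list held more listed genes than others was tested with a one-sided Fisher's exact test that counts every member as tested, which was added after seeing the data. The lists cover the MAF relatives, enterocyte transcription factors, endocytosis, lysosomes, autophagy, suckling and adult stages, lipid, sugar, peptide, cholesterol, bile acid, iron and calcium handling, villus tip, brush border, antimicrobial, stress, NRF2, immediate early, interferon, oxidative phosphorylation and proliferation genes, and markers of stem, goblet, enteroendocrine, tuft, Paneth, immune, fibroblast, smooth muscle, endothelial, neural, erythroid and pancreatic acinar cells.

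Named genes were Mafb and Maf, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 normalized counts, a gene symbol that is no clone name, predicted name or pseudogene and groups that do not overlap, up to 4 called members of each list by size of change with the same minimum or, in a list with no such member, up to 2 of highest mean, and the 3 called genes of highest mean. Other genes are said to be named after their values were seen, and every family gene named in the closing section was chosen in that way. Further alternatives were DESeq2 1.42.0 with the deposited size factors, no filter, a mean of at least 50 normalized counts, stricter thresholds, protein-coding genes alone, each library left out in turn and the replicate number as a block. Xist status as a covariate and a fit of the Xist-low libraries alone were added after seeing the data, with libraries above 500 normalized counts taken as Xist-high. No control was Xist-high, so in both fits the genotype difference is read from DKO replicate 3 against the 3 controls. The pseudocount alternatives were not needed because counts were present.

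The procedure was tested on simulated counts drawn from the means and dispersions of this comparison, with 3366 genes tested. Of these, 67 were changed by 0.585 on the log2 scale, 67 by 1 and 66 by 2. Far fewer genes were changed than passed in the data, so the adjustment over 15021 genes was stricter in the simulation. Its recovery and false calls therefore do not give those of the real test. The fit recovered 28.4% of genes changed by 0.585 on the log2 scale, 77.6% of those changed by 1 and 98.5% of those changed by 2, and called 2 of 3166 genes simulated with no change. A simulated list of lower genes was called lower, and 0 of 30 lists with no change were called. The position of called genes was compared across chromosomes by two-sided Fisher's exact tests against the 55450 genes of GENCODE M21. The design had named the other tested genes as background, but these are not in the table. Values of genes with near-identical copies or overlapping partners are given as uncertain, because how the authors' counting treated shared reads is not given in the sources used here.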

Results

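RNA-seq was performed on small-intestinal epithelial cells of mice at postnatal day 7, an age at which pups still suckle. In 3 mice, Villin-Cre, a recombinase active in the intestinal epithelium, was combined with floxed alleles of Mafb and Maf (the gene for c-Maf), which encode related bZIP transcription factors. These libraries are called the Maf double knockout (DKO). The 3 control mice carried the same floxed alleles without Cre. Each library came from 1 mouse, with cells of the upper, middle and lower small intestine combined. Library totals recovered from the deposited FPKM values were 14441272 to 17325070 in DKO and 18169623 to 19973471 in controls. The deposited table lists only genes that the authors had called different, 1694 higher and 1731 lower in DKO (highest deposited adjusted p 0.0498). The reads of these listed genes came to 43.5% to 46.4% of the recovered total of each library. Genes outside the list were not analysed here, so nothing is said of how they behaved.

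The first comparison asked whether both targeted genes were lost in the libraries labelled DKO. Mafb and Maf fell in all 3 DKO libraries relative to all 3 controls. Mafb (ENSMUSG00000074622, chromosome 2, 160363703 to 160367065, minus strand) went from 4287 ± 1705 normalized counts in controls to 92.6 ± 94.6 in DKO (SD, n = 3 each), a 46.3-fold lower mean. Maf (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794, minus strand) went from 8008 ± 3152 to 258 ± 285 normalized counts, a 31.0-fold lower mean. The coordinates are those of the deposited table, whose positions fit the mouse build GRCm38. The fitted log2 fold change in edgeR was -5.51 (SE 0.66, adjusted p = 0.00106) for Mafb and -4.94 (SE 0.76, adjusted p = 0.00321) for Maf. Within DKO, replicate 3 held more reads of both genes than the other libraries, with 202 normalized counts of Mafb against 33.9 and 42.1 and 586 of Maf against 65.6 and 123. Without that library the log2 fold change was -6.82 for Mafb and -6.42 for Maf.

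**Figure D1:**
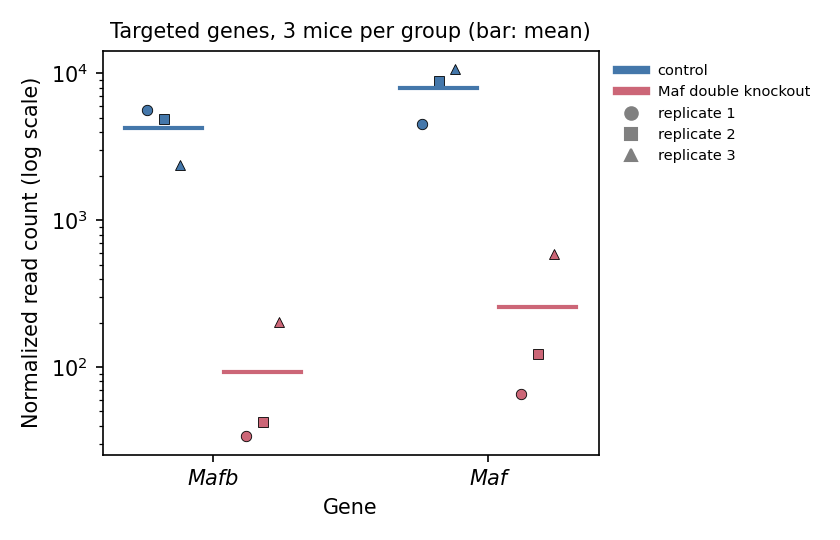
Normalized read counts (log axis) of Mafb and Maf in each of the 6 libraries, with a bar at the mean of each group. The DKO libraries lie between 33.9 and 202 for Mafb and between 65.6 and 586 for Maf, and the lowest controls lie at 2368 and 4526.

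The second comparison asked which other transcripts differed between DKO and control epithelium. Of the listed genes, 2632 passed the edgeR test, with 1284 higher and 1348 lower in DKO. A log2 change of at least 1 in size was seen for 1037 of them, 402 higher and 635 lower. No called gene had the opposite sign in the authors' deposited table. Both used the same counts, size factors and groups, so the signs are no separate check. The groups did not overlap for 2627 of the 2632 called genes, where chance gives 10% for 3 against 3, although the list itself had been selected on these libraries. The first principal component of the listed genes held 87.1% of the variance and separated DKO from control. These genes had been selected as different between the same groups, so such a component was to be found whatever the size of the effect among all genes.

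The count of called genes fell from 2632 to 1740 without DKO replicate 1, to 1559 without control replicate 2 and to 1522 without control replicate 3. The libraries also differed in Xist, the RNA that coats an inactive X chromosome, with 3530 and 4163 normalized counts in DKO replicates 1 and 2, 18.1 in DKO replicate 3 and 5.42 to 20.1 in controls. Sex is not given in the labels, and with Xist status as a covariate, an alternative chosen after seeing the data, 838 genes passed. No control was Xist-high, so under this covariate the genotype difference is read from DKO replicate 3 against the 3 controls. A fit of the Xist-low libraries alone, 1 DKO against 3 controls, has no replicate on the DKO side. In both fits the log2 fold change was -4.41 for Mafb and -3.77 for Maf, so they are not separate checks.

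The largest falls were in genes of varied function. Rarres1 went from 338 ± 165 normalized counts in controls to 2.66 ± 2.45 in DKO (SD, n = 3 each), with log2 fold changes between -7.66 without DKO replicate 2 and -6.38 without DKO replicate 3. Igf2, a fetal growth factor, fell 53.1-fold (169 ± 27.4 to 3.18 ± 1.60). Igf2os, transcribed from the opposite strand of the same locus, fell 47.4-fold. The pair overlaps and the strandedness of the counting is not given in the sources used here, so reads of the one cannot be separated from the other. Stab2, a scavenger receptor, fell 51.2-fold (128 ± 21.3 to 2.49 ± 1.48) and Thbs1, which encodes the matrix glycoprotein thrombospondin 1, fell 30.3-fold (173 ± 19.9 to 5.71 ± 1.16). The adjusted p of these genes in edgeR ranged from 6.1e-05 for Thbs1 to 0.000401 for Rarres1.

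The largest rises included transporters and metabolic enzymes. Fabp6, the ileal bile acid binding protein, rose from 44.7 ± 10.6 normalized counts to 3664 ± 4063 (SD, n = 3 each, adjusted p = 0.00676). Its DKO libraries ranged widely, from 240 in replicate 3 to 2600 in replicate 1 and 8154 in replicate 2, and its log2 fold change moved from 6.36 to 4.99 without DKO replicate 2. With Xist status as a covariate its log2 fold change was 2.42 (SE 0.58, adjusted p = 0.0537), which reads the low value of DKO replicate 3 against the controls. Slc25a45, a mitochondrial carrier, rose 35.3-fold (16.6 ± 6.71 to 584 ± 308). Cyp2b10, a cytochrome P450, rose 34.2-fold (11.3 ± 7.89 to 385 ± 155), with a log2 fold change of 5.09 that became 5.78 without control replicate 3. Aqp3, a water and glycerol channel, rose 20.3-fold (92.8 ± 45.1 to 1883 ± 354), and Rasal1 rose 14.4-fold and Ubd, which encodes a ubiquitin-like modifier, 14.3-fold. Eno1b, a near-identical copy of the enolase gene Eno1, was read at 857 and 791 normalized counts in DKO replicates 2 and 3 and at 14.8 in DKO replicate 1, against 8.13 to 11.5 in controls, and is uncertain because the copies can share reads. Its call ended without control replicate 2 (adjusted p = 0.0665) or control replicate 3 (adjusted p = 0.0606).

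Genes of the endocytic and lysosomal system, through which suckling enterocytes take up and break down milk protein, fell together. Of 42 lysosomal hydrolases and activators, 37 were listed and all of these were lower in DKO, and 35 fell (37 when adjusted over the list alone). Here and below, counts adjusted over the list alone are mostly fixed by the selection of the listed genes and add no separate support. The protease genes Lgmn and Ctsl, encoding legumain and cathepsin L, fell 27.6-fold and 16.1-fold, Lgmn from 56420 ± 14700 to 2043 ± 740 normalized counts and Ctsl from 88530 ± 2402 to 5490 ± 2556 (SD, n = 3 each). Naga and Ctsh fell 6.57-fold and 6.35-fold. The list test (camera, preset correlation), which compares a list's members with the other listed genes, gave an adjusted p of 2.71e-09, and adjusted p = 0.431 with an estimated correlation. Of the hydrolase genes, 33 passed as lower with Xist status as a covariate.

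Of 29 genes for the lysosomal membrane and its acidification, 21 were listed and 17 fell (21 when adjusted over the list alone). The sialic acid exporter gene Slc17a5 fell 16.5-fold, from 25020 ± 4289 to 1516 ± 464 normalized counts (SD, n = 3 each). The proton pump subunit gene Atp6v0a1 fell 2.82-fold, the cation channel gene Mcoln3 2.40-fold and Cln3 2.32-fold. The list was lower at an adjusted p of 0.000275 by camera, and adjusted p = 0.452 with an estimated correlation. With Xist status as a covariate, 9 of these genes passed as lower.

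Of 20 genes for the endocytosis of macromolecules, 10 were listed and all 10 fell, both over all genes and when adjusted over the list alone. Fcgrt, which encodes the neonatal Fc receptor that carries maternal IgG, fell 3.66-fold from 117700 ± 1002 to 32120 ± 3600 normalized counts (SD, n = 3 each). Mamdc4, which encodes endotubin of the apical endosomal complex and was among the 3 most abundant called genes, fell 2.19-fold from 127500 ± 10450 to 58160 ± 10380. Lrp2, encoding the receptor megalin, fell 38.6-fold from 489 ± 292 to 12.7 ± 6.77, with a log2 fold change of -5.29 that became -4.68 without control replicate 1. Clcn5 and Ehd1 fell 3.05-fold and 2.23-fold. The list was lower at an adjusted p of 0.00209 by camera, and adjusted p = 0.431 with an estimated correlation. Under the Xist covariate, 7 of these genes passed as lower.

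Of 23 genes of autophagy and the TFEB pathway, 9 were listed and 7 fell (8 when adjusted over the list alone), among them Flcn, which encodes folliculin, 1.46-fold. This list was lower at an adjusted p of 0.0293, and adjusted p = 0.431 with an estimated correlation, and its call was also lost at a preset correlation of 0.05 (adjusted p = 0.064) and in both rank versions of the test (adjusted p = 0.169 and 0.298). The number of its genes that fell was 3 without DKO replicate 1, 3 without DKO replicate 2, 4 without control replicate 2 and 1 without control replicate 3. With Xist status as a covariate 0 of its genes passed edgeR. All 9 were still fitted lower, at a median log2 fold change of -0.40 against -0.52 without the covariate. Here and below, a direction kept under the covariate was favoured by the selection of the listed genes, which used DKO replicate 3.

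**Figure D2:**
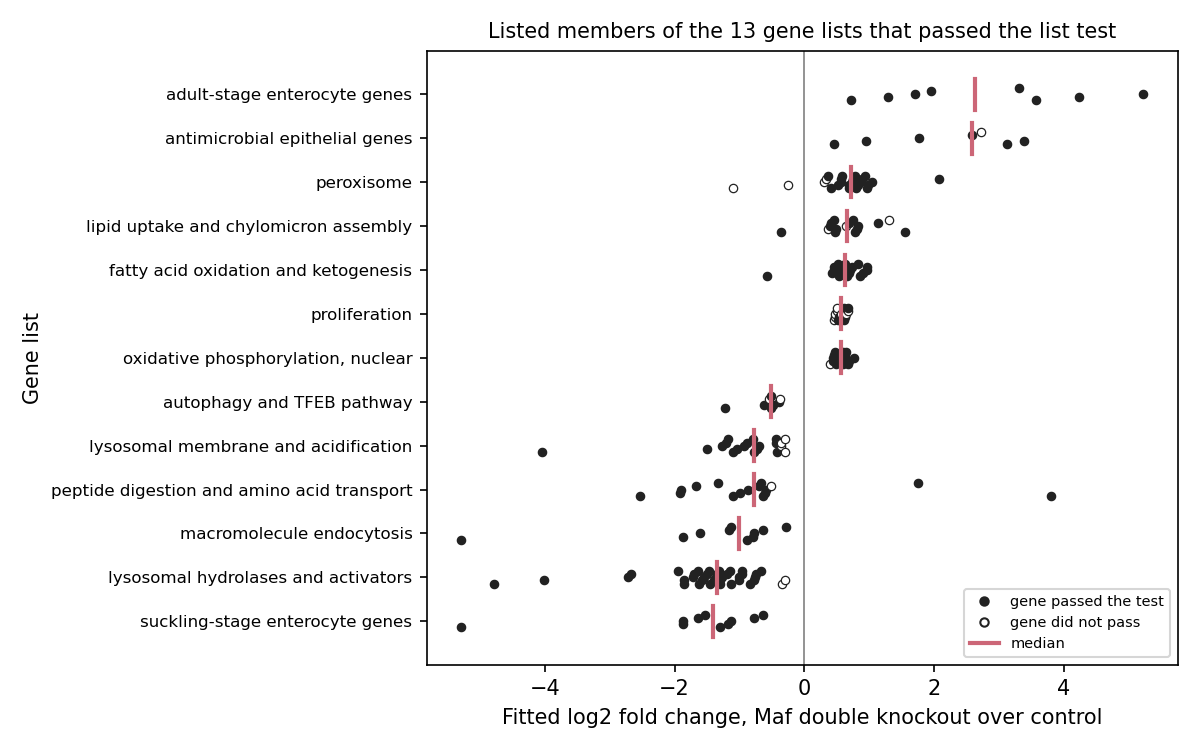
Fitted log2 fold changes, DKO over control, of the listed members of each of the 13 gene lists that passed the list test, with filled points for genes that passed the edgeR test, open points for the others and a line at the list's median. The medians run from -1.41 for the suckling-stage genes to 2.63 for the adult-stage genes.

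Genes known for the suckling stage fell while genes known for the adult stage rose. Of 11 suckling-stage enterocyte genes, 10 were listed and all 10 fell, also when adjusted over the list alone, although 9 of the 11 also stand in other lists. The milk sugar enzyme lactase, encoded by Lct and named after its values were seen, fell 2.26-fold from 51140 ± 10370 to 22600 ± 2684 normalized counts (SD, n = 3 each). Ass1, an enzyme of arginine synthesis, fell 3.67-fold from 11900 ± 1781 to 3239 ± 373, and the lysosomal galactosidase gene Glb1 fell 3.12-fold. Prdm1, encoding the repressor Blimp-1 that holds the suckling program, fell 1.71-fold, a call that ended without control replicate 2 (adjusted p = 0.0504). The list was lower at an adjusted p of 0.000789 by camera, and adjusted p = 0.431 with an estimated correlation. Under the Xist covariate, 9 of these genes passed as lower.

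Of 9 adult-stage enterocyte genes, 8 were listed and all 8 rose, also when adjusted over the list alone. Sis, encoding sucrase-isomaltase (chromosome 3, 72888557 to 72967863), rose 37.5-fold from 197 ± 57.2 to 7378 ± 447 normalized counts (SD, n = 3 each, adjusted p = 3.54e-05). Treh, encoding trehalase, rose 9.91-fold from 397 ± 101 to 3937 ± 1126, Arg2, encoding arginase 2, 18.9-fold from 35.2 ± 19.6 to 666 ± 87.9, and the alkaline phosphatase gene Akp3 11.9-fold from 13.0 ± 2.41 to 155 ± 48.4. The immunoglobulin receptor gene Pigr, chosen after its values were seen, rose 3.25-fold. The list was higher at an adjusted p of 0.000565 by camera, and adjusted p = 0.431 with an estimated correlation. With Xist status as a covariate, 7 of these genes passed as higher.

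**Figure D3:**
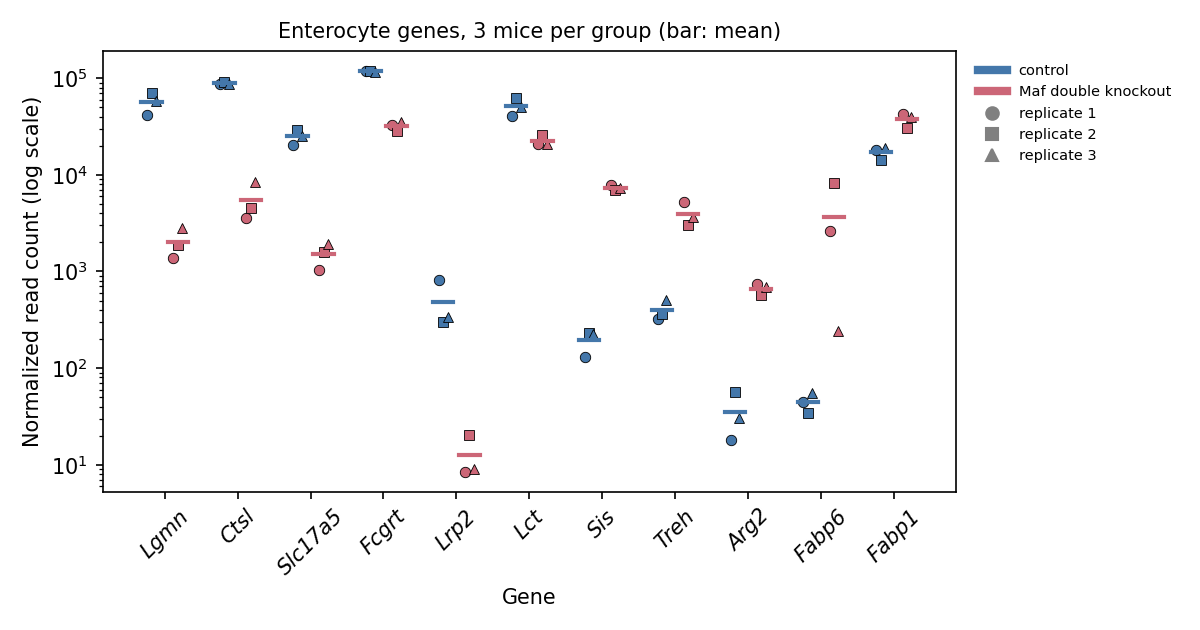
Normalized read counts (log axis) of 11 enterocyte genes in each of the 6 libraries, with a bar at the mean of each group. The DKO libraries of Sis sit between 6944 and 7837 and its controls between 131 and 233, and Fabp6 spreads from 240 to 8154 within DKO.

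Nutrient digestion and uptake genes moved in both directions. Of 23 genes of peptide digestion and amino acid transport, 16 were listed, 13 fell and 2 rose (16 passed when adjusted over the list alone). Ace, a brush border peptidase, fell 5.77-fold from 41080 ± 4591 to 7114 ± 661 normalized counts (SD, n = 3 each), the aminopeptidase gene Enpep fell 3.76-fold and the cystine transporter gene Slc7a9 fell 3.73-fold. The 2 that rose were Ggt1, a glutathione-cleaving enzyme of the cell surface, with a log2 fold change of 3.80 from 387 ± 71.4 to 5400 ± 1292, and Slc6a20a, a proline transporter named after its values were seen, 3.38-fold. The list was lower at an adjusted p of 0.013 by camera, and adjusted p = 0.431 with an estimated correlation, and its call was also lost at a preset correlation of 0.05 (adjusted p = 0.0527). Under the Xist covariate, 7 of these genes passed as lower.

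Of 16 genes of carbohydrate digestion and sugar metabolism, 12 were listed, 8 rose and 4 fell, and all 12 passed when adjusted over the list alone. Besides Sis and Treh, the fructose transporter gene Slc2a5 rose 3.87-fold from 431 ± 47.0 to 1667 ± 84.4 normalized counts (SD, n = 3 each), and Slc5a4b, a member of the sodium-glucose transporter family, rose with a log2 fold change of 3.80. Slc5a4b has a close neighbouring copy, Slc5a4a, that can share reads, so its value is uncertain. The 4 that fell, named after their values were seen, were Lct and the gluconeogenic enzyme genes Fbp1 (3.76-fold), G6pc (2.16-fold) and Pck1 (1.72-fold). As a list they did not pass (adjusted p = 0.129).

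Genes of lipid handling and mitochondrial energy metabolism rose by smaller factors. Of 27 genes of fatty acid oxidation and ketogenesis, 19 were listed, 18 rose and 1 fell (19 passed when adjusted over the list alone). The oxidation enzyme genes Decr1, Acadm and Acadvl rose 1.95-fold, 1.87-fold and 1.81-fold, Decr1 from 2873 ± 188 to 5607 ± 389 normalized counts (SD, n = 3 each). The 1 that fell, named after its value was seen, was Acsl1, a fatty acid activating enzyme, 1.49-fold. The list was higher at an adjusted p of 0.000608 by camera, and adjusted p = 0.431 with an estimated correlation. With Xist status as a covariate, 8 of these genes passed as higher.

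Of 51 peroxisome genes, 24 were listed and 20 rose (23 passed when adjusted over the list alone). The thiolase gene Acaa1b, which has a close copy in Acaa1a and is uncertain for that reason, rose 4.22-fold, the transporter gene Abcd3 2.06-fold, the division factor gene Pex11a 1.98-fold and Hsd17b4, an enzyme of peroxisomal oxidation, 1.96-fold. As a list they were higher at an adjusted p of 0.000333 by camera, and adjusted p = 0.431 with an estimated correlation. Under the Xist covariate, 10 of these genes passed as higher.

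Of 21 genes of lipid uptake and chylomicron assembly, 16 were listed, 12 rose and 1 fell (16 passed when adjusted over the list alone). The fatty acid transporter genes Slc27a2 and Slc27a4 rose 2.94-fold and 1.78-fold, the fatty acid binding protein gene Fabp1 rose 2.21-fold from 17080 ± 2451 to 37680 ± 6097 normalized counts (SD, n = 3 each), and Surf4, a cargo receptor of the secretory pathway, 1.76-fold. The 1 that fell was Plin3, 1.28-fold, named after its value was seen, and its call ended without any 1 library except DKO replicate 3, with adjusted p from 0.0726 to 0.0849. The apolipoprotein genes Apoa4 and Apoa1, the most abundant called genes, rose 1.39-fold and 1.40-fold, to 421300 ± 15640 and 348500 ± 19300 normalized counts. Their calls each ended without DKO replicate 1 (adjusted p = 0.066 and 0.0601), control replicate 2 (0.0682 and 0.0769) or control replicate 3 (0.0537 and 0.0536), and that of Apoa4 also without DKO replicate 3 (0.0503) or control replicate 1 (0.0812). The list was higher at an adjusted p of 0.00247 by camera, and adjusted p = 0.431 with an estimated correlation. The number of its genes that rose was 7 without control replicate 3, and 6 passed as higher with Xist status as a covariate.

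Of 19 nuclear genes of oxidative phosphorylation, 18 were listed and 17 rose (18 when adjusted over the list alone). The rises were small, at 1.71-fold for the ATP synthase subunit gene Atp5o, 1.61-fold for Cox5a, 1.59-fold for Ndufb8 and 1.56-fold for Uqcrc1. The list was higher at an adjusted p of 0.000452 by camera, and adjusted p = 0.431 with an estimated correlation. The number of its genes that rose was 11 without control replicate 3. Of these genes, 7 passed with Xist status as a covariate, while all 18 were still fitted higher, at a median log2 fold change of 0.57 against 0.56 without it.

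Antimicrobial and proliferation genes were also higher. Of 14 antimicrobial epithelial genes, 7 were listed and 6 rose (7 when adjusted over the list alone). The lectin genes Reg1, Reg3a and Reg3b rose 10.4-fold, 8.76-fold and 6.01-fold, Reg3b from 3180 ± 1340 to 19100 ± 9471 normalized counts (SD, n = 3 each), and these close relatives can share reads. As a list they were higher at an adjusted p of 0.0207 by camera, and adjusted p = 0.431 with an estimated correlation. With Xist status as a covariate, 2 of these genes passed as higher, and the median log2 fold change of the list fell from 2.59 to 1.62. Reg3b fell from 2.59 (SE 0.43) to 1.62 (SE 0.41, adjusted p = 0.0651).

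Of 22 proliferation genes, 15 were listed, all with higher means in DKO, and 6 rose (15 when adjusted over the list alone). Their median log2 fold change was 0.56. The list was higher at an adjusted p of 0.00507 by camera, and adjusted p = 0.431 with an estimated correlation, and its call was also lost in the rank version of the test (adjusted p = 0.124). The number of its genes that rose was 2 without DKO replicate 1, 2 without DKO replicate 2 and 0 without control replicate 3, and 0 passed edgeR with Xist status as a covariate, while all 15 were still fitted higher, at a median of 0.40. Of 10 stem cell markers, Axin2 and Lgr5 were listed and fell, 1.86-fold and 1.43-fold (2 when adjusted over the list alone). The call of Lgr5 ended without DKO replicate 1 (adjusted p = 0.0769), control replicate 2 (0.0947) or control replicate 3 (0.0892). Both were still fitted lower under the Xist covariate, but neither passed. The log2 fold change of Axin2 was -0.91 (SE 0.22, adjusted p = 0.0522) against -0.89 (SE 0.14) without it, and that of Lgr5 -0.47 (SE 0.19, adjusted p = 0.287) against -0.52 (SE 0.13).

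Stress and redox genes moved both ways. Of 12 NRF2 targets, 9 were listed, 6 rose and 2 fell (9 passed when adjusted over the list alone). The quinone reductase gene Nqo1 rose 2.55-fold from 348 ± 45.2 to 886 ± 82.1 normalized counts (SD, n = 3 each), and the glutathione transferase genes Gsta1 and Gstm1, which have close copies, rose 5.29-fold and 2.17-fold. The heme oxygenase gene Hmox1 fell 4.64-fold from 415 ± 103 to 89.5 ± 27.9. The number of these genes that fell was 1 without DKO replicate 1, DKO replicate 2, control replicate 2 or control replicate 3. Of 12 genes of the integrated stress response, 7 were listed, 3 rose and 3 fell (7 passed when adjusted over the list alone). Among them Phgdh, an enzyme of serine synthesis, fell 3.85-fold and Sesn2 2.90-fold. The number that rose was 1 without control replicate 1 and 1 without control replicate 3. Neither list passed (adjusted p = 0.249 and 0.883), and for the stress response list the median log2 fold change was 0.69, the mean -0.09 and the test direction higher.

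Among 11 related MAF, CNC and BACH factors, which share dimer partners or binding sites with the targeted pair, 4 were listed and all 4 changed, also when adjusted over the list alone. Mafg fell 2.11-fold from 1850 ± 178 to 875 ± 138 normalized counts and Bach1 fell 1.80-fold from 4723 ± 792 to 2631 ± 527 (SD, n = 3 each). Nfe2l2, encoding NRF2, rose 1.71-fold from 1953 ± 194 to 3347 ± 396. Maff fell 1.73-fold, a call that ended without DKO replicate 2 (adjusted p = 0.0584), control replicate 1 (0.0543), control replicate 2 (0.13) or control replicate 3 (0.0921). Under the Xist covariate Mafg alone passed, and Bach1 (log2 fold change -0.54 against -0.84 without it, adjusted p = 0.194), Maff (-0.51 against -0.79, adjusted p = 0.56) and Nfe2l2 (0.63 against 0.78, adjusted p = 0.0617) kept their direction. Of 22 enterocyte transcription factors, 4 were listed and Prdm1 alone of these fell (1 when adjusted over the list alone). Neither list passed (adjusted p = 0.484 and 0.619).

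The remaining epithelial lists held few listed genes. Of 7 genes of ileal bile acid handling, Fabp6 rose and Fgf15, the ileal hormone that represses bile acid synthesis, fell 5.70-fold from 2185 ± 494 to 384 ± 131 normalized counts (SD, n = 3 each, 2 when adjusted over the list alone). Of 8 genes of duodenal iron and calcium uptake, 4 were listed and 2 fell (4 when adjusted over the list alone), the iron transporter genes Slc11a2, 2.06-fold, and Slc40a1, 1.51-fold, and the list did not pass (adjusted p = 0.129). Of 12 brush border genes, 7 were listed, 3 rose and 4 fell (7 when adjusted over the list alone), and the list did not pass (adjusted p = 0.794). The myosin gene Myo1a rose 1.82-fold and the actin bundler gene Pls1 fell 1.67-fold, and the number of brush border genes that rose was 1 without any 1 of the 6 libraries. Of 8 villus tip genes, 4 were listed and 3 rose (3 when adjusted over the list alone), led by the adenosine deaminase gene Ada at 10.1-fold, whose log2 fold change of 3.34 became 4.10 without control replicate 3. The list did not pass (adjusted p = 0.129), and its genes that rose numbered 2 without DKO replicate 2 and 1 without any other library.

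Of 25 cholesterol synthesis genes, 4 were listed and 2 rose (1 when adjusted over the list alone), among them Insig1 (998 ± 64.8 to 1994 ± 572 normalized counts, SD, n = 3 each), with 1 without DKO replicate 1, control replicate 2 or control replicate 3. Without DKO replicate 3, 1 cholesterol gene passed as lower, where 0 had. Of 11 immediate early genes, 4 were listed, 1 rose and 2 fell (4 when adjusted over the list alone), among them Jun, which fell 1.67-fold. The number that rose was 0 without any 1 of the 6 libraries, and the number that fell was 1 without any 1 library except DKO replicate 2. Of 12 interferon response genes, 4 were listed and Ifit2 alone of these fell, 3.11-fold (3 passed when adjusted over the list alone), a call that ended without control replicate 2 (adjusted p = 0.0643) or control replicate 3 (0.0567). Without DKO replicate 2, 2 interferon genes passed as higher, where 0 had. None of these 3 lists passed (adjusted p = 0.471, 0.413 and 0.618).

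Markers of other cell types were sparse in the list. Of 9 goblet cell markers, 3 were listed and all 3 rose (3 when adjusted over the list alone), with Zg16, a lectin-like secreted protein gene, 4.29-fold higher at 6429 ± 1946 against 1498 ± 822 normalized counts (SD, n = 3 each). Without control replicate 3, 1 goblet gene passed, and under the Xist covariate 0 passed, with all 3 still fitted higher (Zg16 log2 fold change 2.34, SE 0.55, adjusted p = 0.0509, against 2.10, SE 0.44, without it). Of 18 enteroendocrine markers, 4 were listed, Chgb rose 1.46-fold and Nts fell 1.79-fold (2 when adjusted over the list alone), and each call ended in leave-one-out fits without DKO replicate 1 (adjusted p = 0.0633 and 0.0935), control replicate 1 (0.0742 and 0.0804) or control replicate 3 (0.102 and 0.0573). That of Nts also ended without DKO replicate 3 (0.0522) or control replicate 2 (0.0947), and without DKO replicate 2 the number that fell was 2. The list did not pass (adjusted p = 0.876), with a median log2 fold change of -0.04, a mean of -0.04 and a test direction of higher.

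Of 17 immune cell markers, 4 were listed, 2 rose and 1 fell (3 when adjusted over the list alone), and the list did not pass (adjusted p = 0.421). The T cell gene Cd3g rose from 5.49 ± 1.17 to 25.7 ± 7.53 normalized counts (SD, n = 3 each), a low level, and the class II gene H2-Aa rose from 9.02 ± 3.04 to 35.0 ± 19.5, both named after their values were seen. The call of H2-Aa ended without DKO replicate 3 (adjusted p = 0.108), control replicate 1 (0.103), control replicate 2 (0.0961) or control replicate 3 (0.0694). Csf1r, a macrophage receptor gene, fell 1.88-fold, a call that ended without control replicate 2 (adjusted p = 0.0565). Of 8 endothelial markers only Tek was listed, and it rose 3.95-fold (1 when adjusted over the list alone), a call that ended without DKO replicate 1 (adjusted p = 0.0857), control replicate 2 (0.0924) or control replicate 3 (0.0573). Of 9 pancreatic acinar markers, Ctrb1 fell with a log2 fold change of -3.17, from 1762 ± 436 to 196 ± 29.8 normalized counts and Cela1 fell 2.43-fold (2 when adjusted over the list alone), and the call of Cela1 ended without control replicate 3 (adjusted p = 0.057). No marker of tuft cells, Paneth cells, fibroblasts, smooth muscle, enteric neurons and glia, or erythroid cells was listed, and of 5 sex-linked genes only Xist was listed.

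Of 37 lists, 26 had at least 4 tested members, and 13 of these passed, 6 lower and 7 higher, at the preset correlation. With an estimated correlation 0 passed, and 0 had an unadjusted p under 0.05. All 273 tested list genes kept their direction with Xist status as a covariate, which selection on libraries that include DKO replicate 3 had favoured. Their median absolute log2 fold change was 0.75 against 0.78 without it, and their median SE was 0.18 against 0.14, while single lists moved more, such as the antimicrobial genes. For some of the lists without such a count so far, the genes passing under the covariate were 7 higher and 4 lower for carbohydrate digestion, 3 higher and 1 lower for NRF2 targets and 0 higher and 2 lower for the integrated stress response. They were 1 higher and 1 lower for the brush border and for enterocyte transcription factors, 2 higher for villus tip and 1 lower for iron and calcium uptake. Among list genes given here by name without a value under the covariate so far, the calls of Slc40a1, Insig1, Ifit2, Chgb, Csf1r, Cd3g, Tek, Cela1, Gstm1, Enpep, Ndufb8, Acsl1, Plin3, Apoa4, Apoa1 and Flcn were lost. Their adjusted p ran from 0.0507 for Gstm1 to 0.446 for Plin3. The log2 fold change of Cela1 was larger under the covariate (-1.29, SE 0.27, to -1.59, SE 0.41), as were those of Apoa4 (0.47, SE 0.12, to 0.52, SE 0.16), Apoa1 (0.49, SE 0.12, to 0.55, SE 0.15) and Flcn (-0.55, SE 0.11, to -0.59, SE 0.16). Near their former size with a larger error were Tek (1.98, SE 0.49, to 1.78, SE 0.64), Enpep (-1.91, SE 0.29, to -1.82, SE 0.45) and Ndufb8 (0.67, SE 0.12, to 0.64, SE 0.17). Others shrank more, Gstm1 from 1.11 (SE 0.17) to 0.79 (SE 0.19), Acsl1 from -0.57 (SE 0.10) to -0.49 (SE 0.14), Plin3 from -0.36 (SE 0.09) to -0.26 (SE 0.13), Csf1r from -0.91 (SE 0.19) to -0.57 (SE 0.22), Slc40a1 from -0.59 (SE 0.12) to -0.42 (SE 0.15), Ifit2 from -1.63 (SE 0.38) to -1.30 (SE 0.56), Chgb from 0.55 (SE 0.13) to 0.39 (SE 0.17), Cd3g from 2.21 (SE 0.42) to 1.78 (SE 0.58) and Insig1 to 0.61 (SE 0.20).

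By a Fisher's exact test added after seeing the data, 15 lists held more listed genes than the 22.8% of adjusted genes that the table holds. Among them were the lysosomal hydrolases with 88.1% listed (adjusted p = 1.37e-17) and the oxidative phosphorylation genes with 94.7% (adjusted p = 7.4e-10). This test takes genes as independent, whereas the estimated inter-gene correlation was 0.39 in each of these lists. It also does not match genes by read level, so its p-values describe the table only.

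The last comparison asked whether called genes lay on particular chromosomes, as an interval of another strain beside a modified allele would. Both groups carried the floxed alleles, so among the modified alleles only the Cre transgene differed by design. Intervals that differ between single mice are not excluded by this design. Against all genes of the reference annotation, 12 of the tested chromosomes differed from the rest by Fisher's exact test, with more called genes on chromosomes 4, 8, 9, 10, 11, 15 and 19 and fewer on 7, 12, 13, 14 and X. Against protein-coding genes alone 4 did, with more on chromosomes 3 (odds ratio 1.36) and 10 (1.28) and fewer on 2 (0.763) and 7 (0.706). With a log2 change of at least 1 in size chromosome 11 alone did, where 94 such genes lay (odds ratio 1.76, adjusted p = 2.97e-05). Which genes the authors tested is not known, so these backgrounds include genes that could not have been called. Of listed X-linked genes, 77 were lower and 40 higher, against 1647 lower and 1654 higher on autosomes (odds ratio 1.93, Fisher's exact test p = 0.000917), and Xist levels differed between the same libraries.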

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

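The alternatives with TMM, with Xist status and with the Xist-low libraries were chosen after seeing the data, and the others before. The 2632 called genes became 1522 to 2299 when 1 library was left out, in fits with fewer samples. They became 1229 at an adjusted p under 0.01, 1037 with an absolute log2 fold change of at least 1 and 140 with Bonferroni adjustment, which select within the calls. With Xist status as a covariate 838 genes passed, 817 of them shared with the 2632, and with only the Xist-low libraries 1068 passed, 1025 of them shared, both in fits with fewer libraries per genotype and Xist level. With the replicate number as a block 2206 genes passed, 2116 of them shared. The deviations of same-numbered libraries correlated at 0.0612, 0.0013 and 0.0192, and only replicate 1 correlated best with its own number. These values gave little sign of pairing by number, but so few correlations over selected genes cannot exclude it. DESeq2 called 3072 genes, and TMM called 2614 while moving the median log2 fold change of the listed genes by -0.01 and the share of higher calls from 48.8% to 46.4%. The list tests gave 13 calls in every fit that left out a library, 11 at a preset correlation of 0.05, 11 in the rank version and 0 with an estimated correlation. In the 13 called lists the estimated correlation ran from 0.11 to 0.59 against the preset 0.01. The preset p-values of camera thus take as nearly independent genes that varied together. The cause of the 2 lower counts of 11 was not tested. The chromosome test gave 4 chromosomes for protein-coding genes and 1 with an absolute log2 fold change of at least 1, against 12, and the cause was not tested. Mafb and Maf did not pass with Bonferroni adjustment in edgeR (adjusted p = 0.344 and 1, at unchanged log2 fold changes of -5.51 and -4.94). They passed at an adjusted p under 0.01, and under 0.05 with DESeq2, both filters, each library left out, the block and TMM. Their log2 fold changes were -6.82 to -5.10 and -6.42 to -4.48 when a library was left out. In both Xist fits, which read DKO replicate 3 against the controls, the values were smaller in size, at -4.41 for Mafb and -3.77 for Maf. Over 146 other named genes in these refits, 1697 of 1896 values kept their direction and call, 199 lost the call and 0 reversed. Nearly all named genes had groups that do not overlap, so the absence of reversals was largely fixed by selection. The losses were uneven. The call was lost for 50 genes under the Xist covariate, 31 without control replicate 3 and 25 without control replicate 2, while DESeq2 kept all 146. Depth limits the genes with few counts. A change of 1 on the log2 scale was recovered for 77.6% of simulated genes, in a simulation with fewer changed genes and a stricter cutoff than the real test.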

Other observations

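The gene families, and the tests of Xist, of the Eno1 copies and of the Maf reads in DKO replicate 3, were chosen after the values were seen; the count over other splits of the libraries was chosen before. The families were picked by gene symbol from the same values, so their counts describe the table and no p-value is given. Of 22 listed cytochrome P450 genes, 15 rose and 3 fell, with Cyp2c65 8.67-fold higher (265 ± 45.4 to 2295 ± 216 normalized counts, SD, n = 3 each), Cyp2d22 8.15-fold and Cyp4a10 5.75-fold. All 9 listed UDP-glucuronosyltransferase genes rose, among them Ugt2b5 4.10-fold. Of 14 listed glutathione S-transferase genes 13 rose, among them Mgst2 2.85-fold, and all 8 aldo-keto reductase, 5 alcohol dehydrogenase and 7 carboxylesterase genes that were listed rose. Adh1 rose 4.65-fold (1259 ± 140 to 5854 ± 283) and Ces2c 3.11-fold. Members of these families have close copies that can share reads.

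Genes for proteasome subunits and mitochondrial ribosomal proteins were higher wherever they were listed. Of 23 listed proteasome genes 16 rose, led by the immunoproteasome genes Psmb8 2.17-fold (1125 ± 79.4 to 2445 ± 122 normalized counts, SD, n = 3 each), Psmb9 1.92-fold and Psmb10 1.68-fold. Of 27 listed mitochondrial ribosomal protein genes 17 rose, among them Mrpl16 1.71-fold. Of 19 listed genes of the Rab group, which direct vesicle traffic, 12 fell and 2 rose, with Rab42 19.6-fold lower (128 ± 64.5 to 6.52 ± 3.83) and Rab3il1 2.09-fold lower. Listed solute carrier genes went both ways, with 46 risen and 35 fallen, and so did ABC transporter genes, with 5 risen and 7 fallen. Under the Xist covariate the calls of Psmb10 (log2 fold change 0.62, SE 0.15, adjusted p = 0.0604, against 0.75, SE 0.12), Mrpl16 (0.66, SE 0.17, 0.0699, against 0.77, SE 0.12), Rab42 (-3.81, SE 0.92, 0.0551, against -4.28, SE 0.60) and Rab3il1 (-0.87, SE 0.27, 0.128, against -1.06, SE 0.19) were lost. No tested member of the 11 families changed sign with TMM over the listed genes, which moved the median log2 fold change by only -0.01.

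Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, called as many as 2632 genes, and the highest of the others called 0. With 10 splits no share under 0.05 can be reached, and the listed genes had been selected on the real split.

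In DKO replicate 3, reads of the targeted genes exceeded those of the other DKO libraries by 3.82% of the control mean for Mafb and 6.14% for Maf. One candidate explanation is a small admixture of cells that kept both genes. Over the 21 other genes that were more than 20-fold lower in DKO replicates 1 and 2, the median excess in replicate 3 was 2.13% of the control mean (bootstrap 95% interval over genes 1.5 to 4.1). These genes were chosen for low values in DKO replicates 1 and 2, which by itself favours an excess in replicate 3. The interval describes genes within 1 library and not the spread between mice. It spans the bound for this explanation, 0.5 times the mean excess of Mafb and Maf. Admixture thus cannot be told apart from other differences of this library. Immune cells that express the genes are another candidate, and the median ratio of replicate 3 to the other DKO libraries over the 4 listed immune markers was 1.38, with Cd3g at 0.658 and H2-Aa at 2.40, while Mafb and Maf stood at 5.31 and 6.22, so 4 markers that go both ways leave this open. Incomplete recombination in that mouse was not tested separately.

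The Xist-high libraries were both DKO, so a difference of sex could account for part of the comparison. Of the 181 genes called at an absolute log2 fold change of at least 3 in DKO replicates 1 and 2 against controls, DKO replicate 3, Xist-low like the controls, lay beyond all 3 controls on the same side for 98.9%, the exceptions being Xist and Tnfrsf13b. For the 77 listed X-linked genes that were lower, replicate 3 showed a median of 0.901 of the log2 change of replicates 1 and 2 (bootstrap interval 0.772 to 1). Both sets come from a list selected on all 6 libraries, which favours genes shared by the 3 DKO libraries, and replicate 3 is the only Xist-low DKO library. Sex and X dosage therefore cannot be told apart from the genotype by these values, and sex stays open as an untested explanation.

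Eno1b and the processed pseudogene Gm4735, copies of Eno1, were read in DKO replicates 2 and 3 but barely in DKO replicate 1. Their share of the reads of the 3 genes was 16.1% (exact binomial 95% interval 15.3 to 17, counting error only) and 15.2% (14.5 to 15.9) in those libraries, 0.226% (0.148 to 0.331) in DKO replicate 1 and 0.2% to 0.334% in controls. The highest share was 80.7 times the lowest, which argues against a fixed share of Eno1 reads being assigned to the copies. The count of 14.8 for Eno1b in DKO replicate 1, near the controls, argues against the genotype alone as the cause. A strain variant of Eno1 that matches the copies may be carried by those mice, and this was not tested because no reads were used here.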
